A study of Mus musculus with 28 samples.

How the data were processed

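Mouse E14 embryonic stem cells were profiled by 3′ digital gene expression RNA sequencing, which reads the ends of polyadenylated transcripts. Per the labels, cells were kept in 2iL (inhibitors of MEK and of GSK3 together with the cytokine LIF), withdrawn from 2iL for 24, 48, 96 or 120 h, or withdrawn for 48 or 96 h and then given 2iL for a further 24 h. These are 7 groups of 4 libraries, 28 in all. They are called 2iL, 24 h, 48 h, 96 h, 120 h, 48 h + 2iL and 96 h + 2iL here. Each sample title carries an experiment number from 1 to 4, and each experiment holds 1 library of every group. The number was read as marking a shared experiment and is used as the replicate number. The labels do not say whether replicates differ in more than the experiment.

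Per the labels, the authors used bcl2fastq, STAR 2.6.0a and HTSeq with the mm10 build, without stating the role or order of each tool. The deposited file of each library holds raw counts per gene for 31053 genes. Its name calls the counts unique, and whether that refers to alignment position or to molecular identifiers is not stated. The deposited table for the whole series holds CPM, the counts of its 30386 genes scaled to the same total in every library, with no further scaling. In 28 of 28 columns it equalled the CPM computed from the matching count file within a tolerance of 1e-06, and no pair of libraries was identical. The counts were used for every test, and the deposited CPM only for this check and for gene symbols. Gene positions are from GENCODE M21 on GRCm38 (mm10).

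Counts assigned to genes ranged from 1554830 to 2828694 per library, and 13021 to 14923 genes had at least 1 count. Alignments at more than 1 place made up 52.3% to 60.1% of the reads listed in the count files and were not counted. Genes with close copies or pseudogenes, Pou5f1 among them, are therefore undercounted by an unknown amount. Intervals and lower bounds given here cover counting error only and leave out the spread between libraries. Over 42 pairs of replicates the chi-square per gene against sampling noise was 2.39 to 10.3, so the spread exceeds counting error. Reads without molecular identifiers, if none were used, also need not be separate molecules. For a gene with 0 counts in the 4 libraries of a group, the fold is a lower bound taken at 3 counts over that group. The mean of the higher group enters it without its error, so leaving out 1 library can lower the bound. For a gene with 1 to 3 counts, the ratio of pooled counts is given with its exact 95% interval (conditional Poisson test).

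Genes with enough counts were selected with edgeR's filterByExpr by group (at least 10 counts, 15 in total), which left 11080. Library sizes were scaled by TMM, and 1 quasi-likelihood model with a mean per group was fitted to all 28 libraries (edgeR 4.0.16 in R 4.3.3). The 9 contrasts of 2 groups and the difference between the responses to 2iL after 96 h and after 48 h were tested, each two-sided. A gene is said to have risen, fallen or changed where its Benjamini-Hochberg adjusted p over all 11080 genes was under 0.05. Changes are log2 fold changes ± standard error, with 4 libraries in each group, and CPM values are means ± SD over 4 libraries after TMM scaling. The standard error is the absolute change divided by the square root of the F statistic of its test. It is approximate, above all for genes with few counts in a group.

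Gene lists were tested with camera (limma 3.58.1) at a preset correlation between genes of 0.01, adjusted over the 22 lists within each comparison. The 22 lists were naive pluripotency, general pluripotency, formative and primed epiblast, neural progenitor, neuron, mesendoderm and primitive streak, primitive endoderm, trophoblast, two-cell-like, fibroblast (feeder) markers, LIF and STAT3 targets, WNT and beta-catenin targets, MEK and ERK targets, germline genes repressed by DNA methylation, DNA methylation machinery, glycolysis, cholesterol biosynthesis, p53 targets, mitosis and proliferation, mesenchymal and cell adhesion switch, mitochondrially encoded genes, and immediate stress response. They hold 345 different genes, 15 of them in more than 1 list. Beside each call stand the members that rose or fell, adjusted over all genes and over the list alone, and the adjusted p with an estimated correlation where the call is lost with it.

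The lists, the comparisons, the alternatives below except 2, and the rule for named genes were chosen before the data were examined. The rule takes, in each comparison, the 8 genes with the largest rise and the 8 with the largest fall. They must be called, reach a mean of 10 CPM in the higher group and show no overlap between the libraries of the 2 groups. By chance 2.86% of genes show no overlap with 4 against 4. For the difference of responses the overlap condition was dropped. Symbols of the Gm, mt- and Rik kinds and pseudogenes were passed over. In addition, any member of a list may be named, called or not, and up to 4 called members with the largest change may stand as examples of a list. Genes under neither part belong to lists chosen after their values were seen. The individual results of 2 genes are not reported here, and both genes remain in all tests and counts.

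A retained share was computed for each library. Genes that changed at least 2-fold at 48 h (or 96 h), and the mean levels of 2iL and withdrawn libraries, were taken from the other 3 experiments. The share is the mean over these genes of the signed distance from the 2iL mean, divided by the mean signed distance of the withdrawn libraries, on log2 CPM with a prior count of 2. It is 0 at the 2iL level and 1 at the withdrawn level. Shares of 4 against 4 libraries were compared by a two-sided exact permutation test, whose smallest p is 0.0286. A gene is called reversed where it changed on withdrawal and changed in the opposite direction when 2iL was returned. Since both comparisons share the withdrawn libraries, the count is set beside comparisons that take the withdrawn libraries 2 and 2. Simulated unchanged groups are given too. No gene changed on withdrawal in them, so they cannot show what sharing does among genes that did change.

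The procedure was tested on simulated data in which 200 genes were changed in 48 h libraries. It recovered 21.7% of genes changed 1.5-fold, 50.0% of those changed 2-fold and 87.1% of those changed 4-fold, with 3 false calls among 103. The real 48 h comparison had 3081 calls, where the adjustment is less strict, and the simulation held no differences between experiments. These shares therefore need not hold for the real comparisons. A simulated retained share of 0.4 was recovered as 0.428 and 0.407.

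The pairing by experiment was checked on the residuals of genes after removing group means. The 84 pairs of libraries from the same experiment had a mean correlation across genes of 0.086, and the 252 pairs from different experiments -0.029. Of the 4 pairs of a comparison, 3 were over 0.1 at 24 h against 2iL (highest 0.219) and in 96 h + 2iL against 96 h (0.408) and against 120 h (0.419), and 0 to 2 in the other 6 comparisons of 2 groups. The 84 pairs formed by experiments 1 with 2 or 3 with 4 had a mean of 0.051, and the 168 pairs that join 1 of the first with 1 of the second had -0.068. The residuals of a group sum to 0, so positive and negative mean correlations must nearly balance. The negative means are therefore neither a baseline nor a separate observation. Genes are not independent replicates, so no p is given.

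The alternatives tried were relative log expression size factors, library totals without TMM, no filter, a stricter filter (20 counts in 4 libraries), only the groups compared in the fit, the experiment as a block, DESeq2 1.42.0, limma-voom, a 2-fold minimum, each library or experiment left out in turn, camera with an estimated correlation or with the block, and fry. For the retained share, a prior count of 0.5, other gene selections, the median over genes, and genes that rose or fell separately were tried. The 2 chosen after seeing the data leave out experiment 3, and score each library against its own experiment. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was left out.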

Results

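The data are counts per gene from 28 libraries of mouse E14 embryonic stem cells, 4 in each of 7 groups. Total gene counts per library ranged from 1748315 to 2828694 in 2iL, from 1554830 to 2309926 at 24 h, from 1671969 to 2161363 at 48 h, from 2145440 to 2553721 at 96 h and from 1919171 to 2632457 at 120 h. They ranged from 2043207 to 2419846 in 48 h + 2iL and from 1591157 to 2405164 in 96 h + 2iL. The first principal component of log2 CPM held 45.4% of the variance and the second 14.3%. Transcripts of the mitochondrial genome made up 2.37% ± 0.27 of counts in 2iL (SD, n = 4), 1.37% ± 0.21 at 120 h and 1.37% ± 0.13 in 96 h + 2iL.

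**Figure D1:**
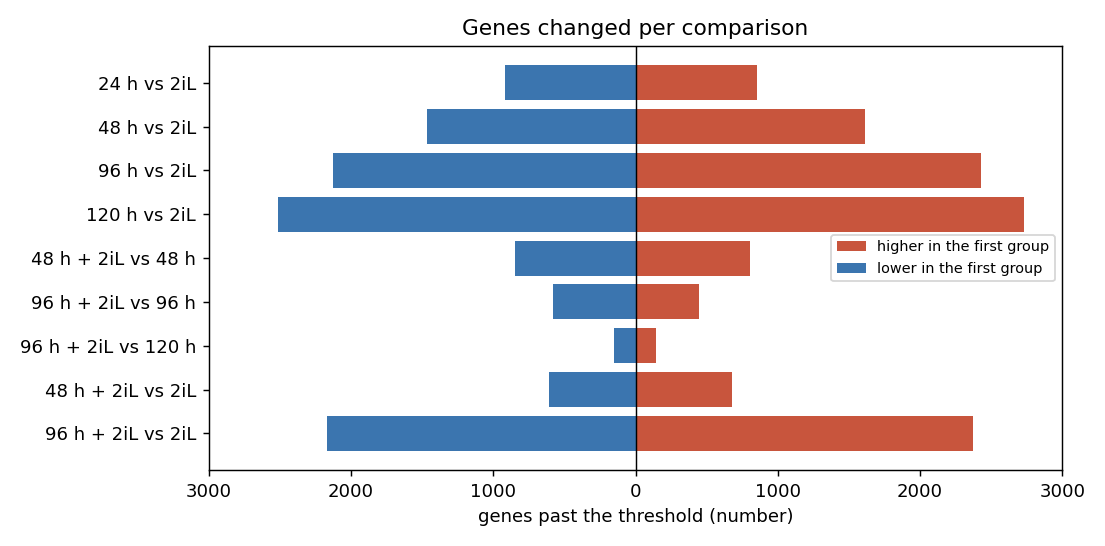
Bars give the number of genes called higher (red) or lower (blue) in the first group of each of 9 comparisons, at an adjusted p under 0.05. The counts run from 142 higher and 149 lower for 96 h + 2iL against 120 h to 2730 higher and 2509 lower for 120 h against 2iL.

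The comparison of 24 h with 2iL asks what the first day without the inhibitors and LIF changed. Tfcp2l1 (chromosome 1, 118627945 to 118685168), a transcription factor of the naive state, fell from 550 ± 68.4 to 66.6 ± 16.3 CPM, and Nanog fell from 148 ± 23.1 to 37.8 ± 12.5 CPM. Pou3f1 (chromosome 4, 124656807 to 124660655) and Otx2 (chromosome 14, 48657677 to 48673819), transcription factors of the epiblast after implantation, rose from 5.83 ± 1.87 to 80.8 ± 24.2 CPM and from 13.5 ± 5.67 to 182 ± 35.9 CPM. The mesoderm factor T (chromosome 17, 8434423 to 8442496) had 173 counts in 2iL and 1 at 24 h, a ratio of 133 (95% interval 23.6 to 5300). Cdx2 (chromosome 5, 147300805 to 147307270), a caudal-type homeobox factor, had 118 counts in 2iL and 1 at 24 h, a ratio of 91.0 (95% interval 16 to 3620).

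At 24 h, 1770 genes changed, 851 up and 919 down, or 679 up and 1034 down with library totals in place of TMM. The rises with the largest fold included the transcription factor gene Bcl11a (log2 fold change 4.16 ± 0.48, adjusted p = 1.74e-07), the fatty acid transporter gene Slc27a2 (4.09 ± 0.56, adjusted p = 2.43e-06) and the calcium release channel gene Ryr3 (4.82 ± 0.73, adjusted p = 1.26e-05). Slc47a1 had 0 counts in 2iL and was at least 38.8-fold higher at 24 h, and Tlx2 had 0 counts at 24 h and was at least 27.7-fold lower. Sp5 (chromosome 2, 70474923 to 70477729), a target of WNT signalling, fell with a log2 fold change of -5.57 ± 0.63 (adjusted p = 1.15e-07).

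Formative and primed epiblast genes rose at 24 h in 12 of 19 cases and fell in 0, the same adjusted over the list alone (camera adjusted p = 1.08e-11). Dnmt3l was at 3.39 ± 0.41 and Sox3 at 2.65 ± 0.44 (log2 fold changes, as for all members of lists). Of 11 general pluripotency genes 8 rose (5 without the 2iL library of experiment 3) and 0 fell, the same adjusted over the list alone (camera adjusted p = 4.84e-05), among them Utf1 (2.65 ± 0.45). In the DNA methylation machinery 4 of 9 measured genes rose and 0 fell, the same adjusted over the list alone (camera adjusted p = 2.98e-05). They were the de novo methyltransferases Dnmt3a (2.25 ± 0.22) and Dnmt3b (2.56 ± 0.33), their cofactor Dnmt3l, and Tet3 (1.22 ± 0.40). Mitosis and proliferation genes rose in 9 of 18 cases and fell in 0, or 11 and 0 adjusted over the list alone (camera adjusted p = 2.38e-05). Cdc20 rose by 0.67 ± 0.14.

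Naive pluripotency genes fell at 24 h in 8 of 17 cases and rose in 1, or 9 and 1 adjusted over the list alone (camera adjusted p = 1.77e-05, adjusted p = 0.192 with an estimated correlation). Prdm14 (-3.55 ± 0.85) and Dppa3 (-2.01 ± 0.50) were among them. Mesendoderm and primitive streak genes fell in 6 of 10 measured cases and rose in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 2.74e-06). WNT and beta-catenin targets fell in 7 of 13 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 1.77e-05, adjusted p = 0.0876 with an estimated correlation). Cdx1 fell in both lists (-4.34 ± 0.74). LIF and STAT3 targets fell in 5 of 14 cases and rose in 0, or 6 and 0 adjusted over the list alone (camera adjusted p = 4.3e-05, adjusted p = 0.0546 with an estimated correlation). The kinase gene Pim1 was at -1.78 ± 0.22. Cholesterol biosynthesis genes rose in 8 of 21 cases and fell in 0, or 9 and 0 adjusted over the list alone (camera adjusted p = 0.000105, adjusted p = 0.141 with an estimated correlation). The count of 8 was 3 to 4 without the 24 h library of experiment 1 or 2 or the 2iL library of experiment 3 or 4. MEK and ERK targets rose in 5 of 15 cases and fell in 2, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0383, adjusted p = 0.0876 with an estimated correlation). The feedback inhibitor genes Dusp4 (3.41 ± 0.62) and Spry4 (2.71 ± 0.59) rose, and the immediate early gene Egr1 fell (-3.88 ± 0.67).

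**Figure D2:**
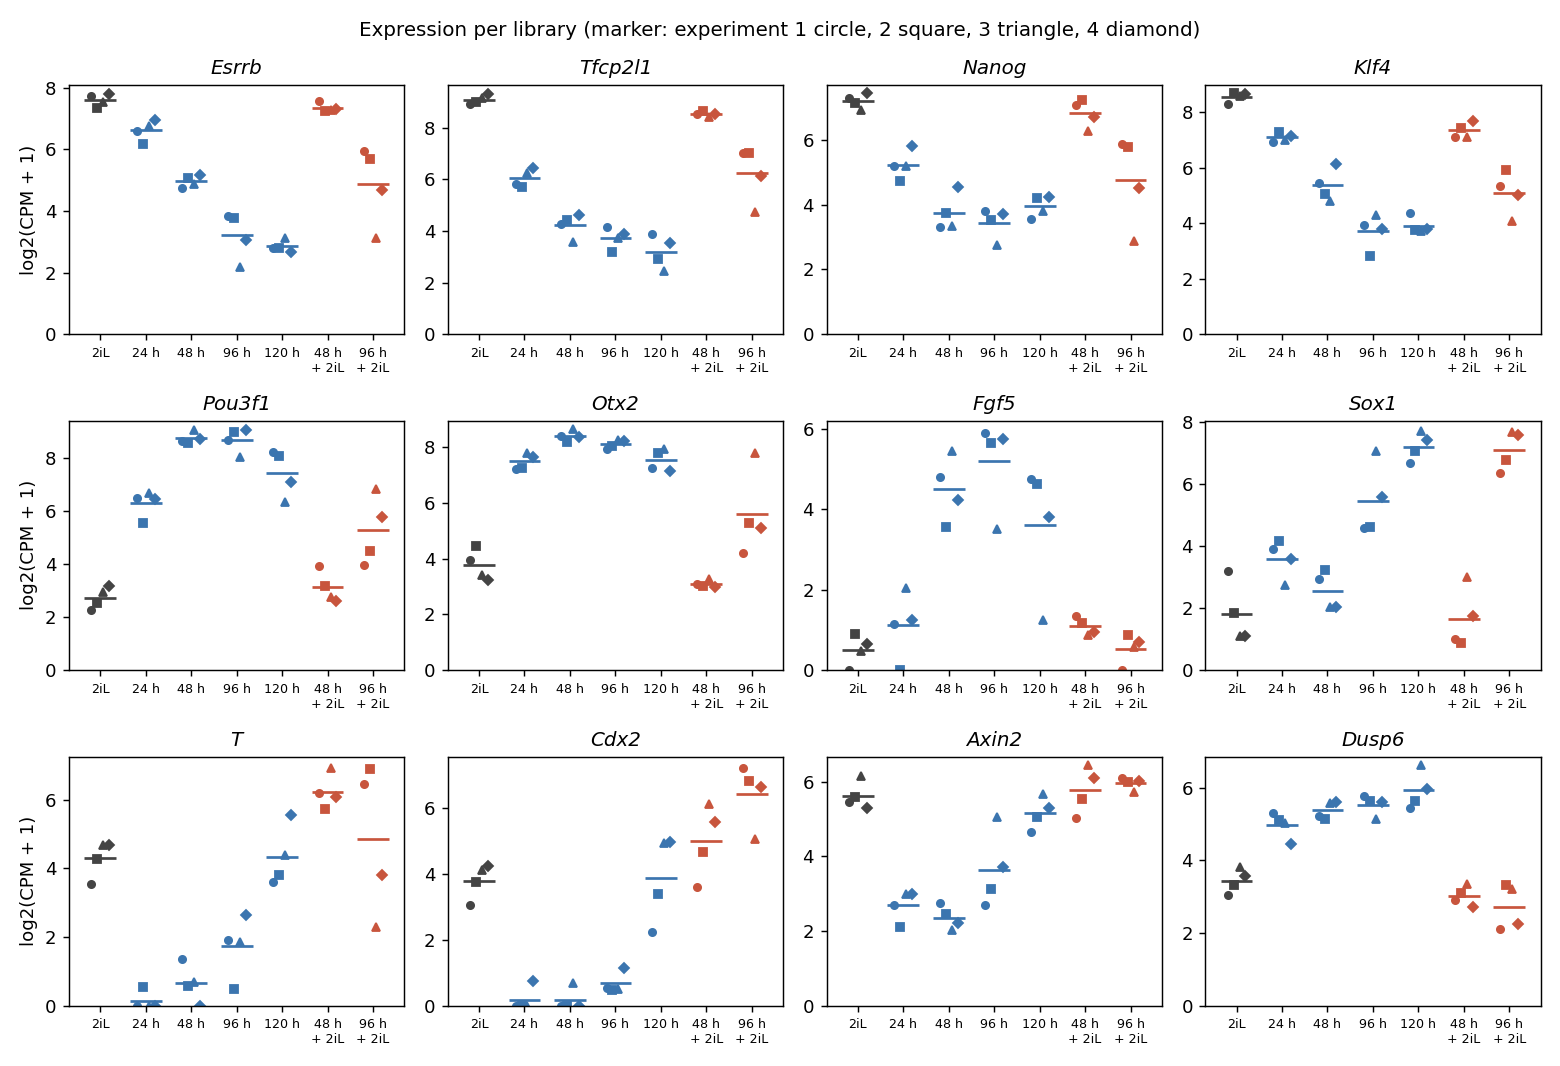
Each panel plots log2 of CPM plus 1 of 1 gene for the 4 libraries of each of 7 groups, with bars at the group means and a marker shape per experiment. Tfcp2l1 averaged 550 CPM in 2iL, 18.3 at 48 h, 373 in 48 h + 2iL and 88.7 in 96 h + 2iL.

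The comparison of 48 h with 2iL follows withdrawal for a further day. Pou3f1 reached 435 ± 69.8 CPM (log2 fold change 6.22 ± 0.51, adjusted p = 3.63e-11), and the growth factor gene Fgf5 (chromosome 5, 98254184 to 98277030) rose from 0.451 ± 0.36 to 24.6 ± 13.8 CPM. Tfcp2l1 fell to 18.3 ± 5.31 CPM, and Esrrb (chromosome 12, 86361117 to 86521628), a nuclear receptor of the naive network, fell from 195 ± 28 to 30.4 ± 4.12 CPM. In all, 3081 genes changed, 1616 up and 1465 down, or 1492 up and 1544 down with library totals, so the balance depends on the scaling. The phosphatase gene Dusp4 was among the largest rises (6.22 ± 0.53, adjusted p = 7.54e-11), as was Myrf, with 183 counts at 48 h and 1 in 2iL (ratio 224, 95% interval 39.6 to 8880). Mal and the water channel gene Aqp3 had 0 counts at 48 h and were at least 73.0-fold and at least 40.8-fold lower. The glutamate receptor gene Grin1 had 3 counts against 429 in 2iL (ratio 117, 95% interval 39.8 to 570).

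At 48 h, formative and primed epiblast genes rose in 15 of 19 cases and fell in 0, or 15 and 1 adjusted over the list alone (camera adjusted p = 3.62e-16). Otx2 rose by 4.66 ± 0.46 and Sox3 by 4.38 ± 0.38. Naive pluripotency genes fell in 15 of 17 cases and rose in 0, the same adjusted over the list alone (camera adjusted p = 3.62e-16). Tbx3 was at -4.12 ± 0.31 and Nanog at -3.50 ± 0.39. Of 14 LIF and STAT3 targets 11 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 3.45e-10). Klf4 was at -3.15 ± 0.27 and Bcl3 at -2.97 ± 0.32. Cholesterol biosynthesis genes rose in 17 of 21 cases and fell in 0, or 18 and 0 adjusted over the list alone (camera adjusted p = 4.47e-08). Lss rose by 1.44 ± 0.21. DNA methylation machinery genes rose in 5 of 9 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.00036). Dnmt3a rose by 3.89 ± 0.23.

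Further lists called at 48 h lost the call with an estimated correlation. Mesendoderm and primitive streak genes fell in 6 of 10 cases and rose in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.000486, adjusted p = 0.117 with an estimated correlation), and WNT and beta-catenin targets fell in 7 of 13 and rose in 1, or 8 and 1 adjusted over the list alone (camera adjusted p = 0.00036, adjusted p = 0.135 with an estimated correlation). Sp5 (-5.94 ± 0.65) and Cdx1 (-4.73 ± 0.76) were among those that fell. General pluripotency genes rose in 7 of 11 cases and fell in 2, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.00502, adjusted p = 0.135 with an estimated correlation). Utf1 was at 3.08 ± 0.45 and the NODAL co-receptor gene Tdgf1 at -1.11 ± 0.36. Mitosis and proliferation genes rose in 8 of 18 cases and fell in 0, or 11 and 0 adjusted over the list alone (camera adjusted p = 0.00485, adjusted p = 0.101 with an estimated correlation). MEK and ERK targets rose in 4 of 15 and fell in 2, the same adjusted over the list alone (camera adjusted p = 0.0445, adjusted p = 0.101 with an estimated correlation).

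The comparison of 96 h with 2iL asks what is different after 4 days. Fgf5 reached 43.1 ± 22.1 CPM, Tfcp2l1 was at 12.8 ± 3.70 CPM and Esrrb at 9.16 ± 4.62 CPM. The neural factor gene Sox1 had a mean of 57.2 ± 52.9 CPM, from 22.9 to 135 in single libraries, against 3.26 ± 3.37 in 2iL. In all, 4557 genes changed, 2430 up and 2127 down. The adhesion gene Nfasc had 0 counts in 2iL and was at least 107-fold higher, and Crxos fell from 300 ± 48.3 to 1.93 ± 0.64 CPM (log2 fold change -7.25 ± 0.47, adjusted p = 6.72e-14).

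Among 17 naive pluripotency genes 16 fell at 96 h and 0 rose, the same adjusted over the list alone (camera adjusted p = 1.95e-22). Tcl1 was at -5.12 ± 0.28 and Klf4 at -4.87 ± 0.30. LIF and STAT3 targets fell in 13 of 14 cases and rose in 0, the same adjusted over the list alone (camera adjusted p = 9.39e-14). Of 19 formative and primed epiblast genes 13 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 6.42e-09). Pou3f1 rose by 6.19 ± 0.51 and Sox3 by 5.51 ± 0.36. Cholesterol biosynthesis genes rose in 16 of 21 cases and fell in 0, or 18 and 0 adjusted over the list alone (camera adjusted p = 2.99e-10). Pmvk rose by 1.95 ± 0.28. Neural progenitor genes rose in 11 of 15 measured cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.00653, adjusted p = 0.456 with an estimated correlation). The forebrain factor gene Six3 was at 5.52 ± 0.75 and Nkx6-2 at -5.78 ± 0.42. The library of experiment 3 stood apart in Zic1, at 6.54 CPM against 0 to 0.918 in the other 3, and in Pax6, at 17.9 CPM against 2.29 to 4.87. WNT and beta-catenin targets fell in 8 of 13 cases and rose in 2, the same adjusted over the list alone (camera adjusted p = 0.011, adjusted p = 0.456 with an estimated correlation). Notum was at -3.50 ± 0.67.

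The comparison of 120 h with 2iL extends withdrawal to 5 days. Zic1 (chromosome 9, 91358058 to 91365810), a factor of the dorsal neural tube, and the ligand gene Wnt1 had 0 counts in 2iL and were at least 82.8-fold and at least 93.7-fold higher. Without the 120 h library of experiment 3 the bound for Zic1 was 44.7. Sox1 rose to 153 ± 46.5 CPM. Pou5f1 was at 8.03 ± 5.17 CPM against 32.5 ± 3.66 in 2iL (log2 fold change -1.98 ± 0.42). In all, 5239 genes changed, 2730 up and 2509 down. Tnni1, a troponin subunit gene, had 0 counts at 120 h and was at least 102-fold lower. Scaling by library totals without TMM shifted the median of all genes by 0.121 (log2), and 61.1% of the calls then rose against 52.1%.

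Neural progenitor genes rose at 120 h in 14 of 15 measured cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 4.23e-05, adjusted p = 0.168 with an estimated correlation). Pou3f2 had 406 counts against 3 in 2iL (ratio 130, 95% interval 44.3 to 635, and 73.4 without the 120 h library of experiment 3). Naive pluripotency genes fell in 16 of 17 cases and rose in 0, the same adjusted over the list alone (camera adjusted p = 5.56e-22). Tcl1 was at -6.37 ± 0.32 and Nr5a2 at -5.21 ± 0.40. Of 14 LIF and STAT3 targets 12 fell and 0 rose, the same adjusted over the list alone (camera adjusted p = 6.21e-13). Bcl3 was at -5.30 ± 0.39. Of 19 formative and primed epiblast genes 13 rose and 3 fell, the same adjusted over the list alone (camera adjusted p = 1.05e-05). Lin28b rose by 4.49 ± 0.40. Cholesterol biosynthesis genes rose in 17 of 21 cases and fell in 0, the same adjusted over the list alone (camera adjusted p = 6.25e-07, adjusted p = 0.079 with an estimated correlation). Hmgcs1 rose by 1.86 ± 0.14. Mitochondrially encoded genes, a list for RNA quality, fell in 6 of 10 measured cases (3 without the 2iL or 120 h library of experiment 3) and rose in 0, the same adjusted over the list alone (camera adjusted p = 0.0384, adjusted p = 0.326 with an estimated correlation). mt-Nd2 was at -1.16 ± 0.14.

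Lists of other cell types and the other lists given next were not called at 120 h. Primitive endoderm genes rose in 3 of 8 measured cases and fell in 3, or 4 and 3 adjusted over the list alone (camera adjusted p = 0.744), and trophoblast genes rose in 3 of 7 and fell in 2, the same adjusted over the list alone (camera adjusted p = 0.856). Fibroblast (feeder) markers rose in 1 of 9 and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.96). Col5a1 rose by 1.52 ± 0.39. The two-cell-like list had 1 measured gene of 16, Gm21761, which fell from 54 counts to 2 (ratio 28, 95% interval 7.39 to 237, and 14.3 without the 2iL library of experiment 4), also adjusted over the list alone (camera adjusted p = 0.652). Neuron genes rose in 5 of 9 cases and fell in 1, the same adjusted over the list alone (camera adjusted p = 0.0722). Elavl3 rose by 3.29 ± 0.49. Germline genes repressed by DNA methylation fell in 2 of 4 measured cases and rose in 0, the same adjusted over the list alone (camera adjusted p = 0.12). Dazl was at -5.64 ± 0.52. Of 19 glycolysis genes 7 rose and 6 fell, the same adjusted over the list alone (camera adjusted p = 0.744). Slc16a3 was at 3.75 ± 0.29 and Pfkp at -3.43 ± 0.28. P53 targets rose in 2 of 16 cases and fell in 7, the same adjusted over the list alone (camera adjusted p = 0.12). Cdkn1a was at -1.69 ± 0.19. Genes of the mesenchymal and cell adhesion switch rose in 8 of 16 cases and fell in 5, or 9 and 5 adjusted over the list alone (camera adjusted p = 0.307). The N-cadherin gene Cdh2 was at 3.93 ± 0.41. Immediate stress response genes, the other list for RNA quality, rose in 2 of 12 cases and fell in 5, or 3 and 5 adjusted over the list alone (camera adjusted p = 0.252). Asns was at -2.11 ± 0.20.

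The comparison of 48 h + 2iL with 48 h asks what changed over 24 h with 2iL returned. It also holds 24 h of further culture, and no group withdrawn for 72 h was analysed here. Tfcp2l1 rose from 18.3 ± 5.31 to 373 ± 25.3 CPM and Nanog (chromosome 6, 122707489 to 122714633) from 13.1 ± 6.19 to 115 ± 32.3 CPM. Pou3f1 fell from 435 ± 69.8 to 8.27 ± 4.11 CPM and Otx2 from 345 ± 47.5 to 7.61 ± 0.79 CPM. T rose from 0.665 ± 0.65 to 77.4 ± 29.0 CPM, above the 19.5 ± 6.54 CPM of 2iL. In all, 1652 genes changed, 802 up and 850 down, or 879 up and 728 down with library totals, so the balance depends on the scaling. Sp5 (log2 fold change 6.54 ± 0.64, adjusted p = 5.77e-09) and the NODAL antagonist gene Lefty1 (chromosome 1, 180935022 to 180938400; 5.29 ± 0.65, adjusted p = 3.83e-07) were among the largest rises. Gad1, which encodes an enzyme of GABA synthesis, had 0 counts at 48 h and was at least 40.2-fold higher, and Cdx2 had 343 counts against 1 (ratio 278, 95% interval 49.6 to 11000).

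Naive pluripotency genes rose in 48 h + 2iL in 11 of 17 cases and fell in 0, or 14 and 0 adjusted over the list alone (camera adjusted p = 1.7e-16). Tfcp2l1 rose by 4.34 ± 0.32 and Gbx2 by 2.88 ± 0.43. Of 19 formative and primed epiblast genes 13 fell and 1 rose, the same adjusted over the list alone (camera adjusted p = 1.7e-16). Fgf5 was at -4.37 ± 0.69 and Grhl2 at -2.73 ± 0.49. Mesendoderm and primitive streak genes rose in 7 of 10 cases and fell in 0, or 9 and 0 adjusted over the list alone (camera adjusted p = 2.63e-12), and WNT and beta-catenin targets rose in 7 of 13 and fell in 0, or 9 and 0 adjusted over the list alone (camera adjusted p = 2.39e-10). Cdx1 is in both lists (5.77 ± 0.73). Of 14 LIF and STAT3 targets 6 rose and 0 fell, or 7 and 1 adjusted over the list alone (camera adjusted p = 3.42e-07). Bcl3 rose by 2.52 ± 0.32. MEK and ERK targets fell in 5 of 15 cases and rose in 0, the same adjusted over the list alone (camera adjusted p = 0.000149). Dusp4 was at -4.21 ± 0.43 and Dusp6 at -2.49 ± 0.29. DNA methylation machinery genes fell in 3 of 9 cases and rose in 0, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.000198), namely Dnmt3a (-2.34 ± 0.21), Dnmt3b (-2.36 ± 0.32) and Dnmt3l (-2.25 ± 0.39). Mitosis and proliferation genes fell in 6 of 18 cases and rose in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.000409). Aurka was at -0.67 ± 0.13.

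In the same comparison, general pluripotency genes fell in 6 of 11 cases and rose in 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.000556, adjusted p = 0.0678 with an estimated correlation). Utf1 was at -3.29 ± 0.45. Cholesterol biosynthesis genes fell in 8 of 21 cases and rose in 0, or 11 and 0 adjusted over the list alone (camera adjusted p = 1.61e-05, adjusted p = 0.0774 with an estimated correlation). Sqle was at -0.84 ± 0.13. Germline genes repressed by DNA methylation fell in 1 of 4 cases, Taf7l at -2.02 ± 0.52, and rose in 0, the same adjusted over the list alone (camera adjusted p = 0.0472, adjusted p = 0.106 with an estimated correlation). With the experiment as a block the adjusted p of that list was 0.0583.

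The comparison of 96 h + 2iL with 96 h asks the same after the longer withdrawal. It too holds 24 h of further culture, which the comparison with 120 h further below matches. Cdx2 rose from 0.629 ± 0.39 to 96.0 ± 47.0 CPM (log2 fold change 7.11 ± 0.70, adjusted p = 7.09e-08), above the 13.4 ± 4.62 CPM of 2iL. The homeobox genes Hoxb1, with 257 counts against 2 (ratio 148, 95% interval 40.4 to 1230), and Hoxb4 (4.41 ± 0.81, adjusted p = 0.000414) also rose. Tfcp2l1 rose from 12.8 ± 3.70 to 88.7 ± 51.0 CPM, and Fgf5 fell from 43.1 ± 22.1 to 0.483 ± 0.35 CPM. In all, 1024 genes changed, 445 up and 579 down, and 658 changed without the 96 h library of experiment 2. Hoxb1 was at 91.9 CPM in the 96 h + 2iL library of experiment 4 and at 11.4 to 23.5 in the other 3, with a ratio of 77.9 without it. At 120 h without 2iL it was already at 12.91 CPM, and 96 h + 2iL against 120 h gave 1.43 (log2, adjusted p = 0.308). Utf1, a chromatin protein gene of pluripotent cells, fell from 252 ± 125 to 14.2 ± 9.14 CPM (-4.10 ± 0.52, adjusted p = 1.81e-06).

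WNT and beta-catenin targets rose in 96 h + 2iL in 10 of 13 cases and fell in 0, or 12 and 0 adjusted over the list alone (camera adjusted p = 1.42e-16). Sp5 rose by 3.70 ± 0.48. Of 10 mesendoderm and primitive streak genes 8 rose and 0 fell, or 8 and 1 adjusted over the list alone (camera adjusted p = 1.78e-09). Evx1 rose by 4.07 ± 0.89 and Lefty1 by 3.97 ± 0.56. Formative and primed epiblast genes fell in 11 of 19 cases and rose in 2, or 13 and 4 adjusted over the list alone (camera adjusted p = 1.78e-09). Pou3f1 was at -3.08 ± 0.40 and Foxd3 at -3.70 ± 0.74. MEK and ERK targets fell in 7 of 15 cases (4 without the 96 h library of experiment 1 or the 96 h + 2iL library of experiment 2) and rose in 0, or 9 and 0 adjusted over the list alone (camera adjusted p = 3.44e-07). Dusp6 was at -2.87 ± 0.30. LIF and STAT3 targets rose in 6 of 14 cases and fell in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 5.39e-06). Klf4 rose by 1.52 ± 0.31, but in experiment 3 it was at 16.06 CPM against 18.75 at 96 h. General pluripotency genes fell in 7 of 11 cases (4 without the 96 h + 2iL library of experiment 3 or the 96 h library of experiment 4) and rose in 0, or 8 and 1 adjusted over the list alone (camera adjusted p = 5.27e-06). L1td1 was at -2.07 ± 0.47.

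Naive pluripotency genes rose in 96 h + 2iL against 96 h in 7 of 17 cases and fell in 0, or 8 and 0 adjusted over the list alone (camera adjusted p = 8.74e-09, adjusted p = 0.0763 with an estimated correlation). Nr5a2 rose by 2.49 ± 0.40 and Esrrb by 1.99 ± 0.36. In experiment 3 Esrrb was at 7.787 CPM against 3.488 at 96 h, Tfcp2l1 at 25.31 against 12.21 and Nanog at 6.327 against 5.669. Neural progenitor genes rose in 6 of 15 cases and fell in 2, or 8 and 2 adjusted over the list alone (camera adjusted p = 0.0096, adjusted p = 0.276 with an estimated correlation, and 0.0534 with fry). Zic1 rose by 3.67 ± 0.73 and Pax3 by 3.24 ± 0.74, with Six3 at -4.69 ± 0.69. At 120 h without 2iL Zic1 was at 28.2 CPM, against 26.6 in 96 h + 2iL, so it reached this level without 2iL too. Pax3 had 64 counts at 120 h and 121 in 96 h + 2iL. Cholesterol biosynthesis genes fell in 5 of 21 cases (2 to 3 without the 96 h library of experiment 2 or 4 or the 96 h + 2iL library of experiment 1 or 2) and rose in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 9.06e-06, adjusted p = 0.0763 with an estimated correlation). Glycolysis genes fell in 5 of 19 and rose in 1, the same adjusted over the list alone (camera adjusted p = 0.00157, adjusted p = 0.149 with an estimated correlation). Slc16a3 was at -1.79 ± 0.25. The count of glycolysis genes that fell was 2 without the 96 h library of experiment 1, 2 or 4 or the 96 h + 2iL library of experiment 2, 3 or 4. Mitosis and proliferation genes fell in 1 of 18 cases, Ube2c at -0.64 ± 0.12, and rose in 0, the same adjusted over the list alone (camera adjusted p = 0.00473, adjusted p = 0.0763 with an estimated correlation). DNA methylation machinery genes fell in 3 of 9 cases and rose in 0, or 3 and 1 adjusted over the list alone (camera adjusted p = 0.0337, adjusted p = 0.0763 with an estimated correlation). Dnmt3b was at -3.26 ± 0.34. The median of that list was 0.13 while its mean was -0.60 and its test pointed down. Mitochondrially encoded genes fell in 3 of 10 cases (0 to 1 without the 96 h library of experiment 1 or 2 or the 96 h + 2iL library of experiment 3 or 4) and rose in 0, or 4 and 0 adjusted over the list alone (camera adjusted p = 0.0134, adjusted p = 0.219 with an estimated correlation). mt-Co1 was at -0.62 ± 0.17.

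The comparison of 96 h + 2iL with 120 h sets re-induced cells beside cells withdrawn for the same total time. Tfcp2l1 (log2 fold change 3.29 ± 0.35, adjusted p = 3.36e-07) and Klf2 (chromosome 8, 72319033 to 72321656; 3.10 ± 0.39, adjusted p = 5.99e-06), both factors of the naive state, were higher with 2iL. Fgf5 was at 0.483 ± 0.35 against 16.1 ± 11.4 CPM (-4.89 ± 0.82, adjusted p = 0.000456, and 0.191 with limma-voom). Wnt1 had 3 counts against 284 (ratio 84.8, 95% interval 28.7 to 413). Sox1 was at 148 ± 61.9 CPM with 2iL and 153 ± 46.5 without (-0.06, adjusted p = 0.971), and Zic1 at 26.6 ± 23.2 and 28.2 ± 26.2 (-0.08, adjusted p = 0.974). In all, 291 genes changed, 142 up and 149 down. The count was 158 without the 96 h + 2iL library of experiment 2, 186 without the 120 h library of experiment 2, 450 without the 96 h + 2iL library of experiment 3, 115 with only the groups compared in the fit and 493 with no filter.

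Other named genes of this comparison were the ligand gene Wnt6 (3.85 ± 0.68, adjusted p = 0.000953), the retinol transporter gene Stra6 (3.14 ± 0.58, adjusted p = 0.00159) and the homeobox gene Hoxb4 (3.33 ± 0.73, adjusted p = 0.00684), which rose. Irs4, an adaptor of insulin signalling (-3.66 ± 0.40, adjusted p = 6.66e-07), and the paired-box gene Pax2 (-3.86 ± 0.72, adjusted p = 0.00155) fell. Wnt7b (-3.54 ± 0.88, adjusted p = 0.0204) lost its call with DESeq2 (0.208) and without the 96 h + 2iL library of experiment 1 (0.0811), 2 (0.0927) or 4 (0.0756) or the 120 h library of experiment 3 (0.0979). Lgi1 (-3.47 ± 0.83, adjusted p = 0.0139) lost it without the 96 h + 2iL library of experiment 2 (0.0685) or the 120 h library of experiment 3 (0.0891).

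Against 120 h, naive pluripotency genes rose in 10 of 17 cases and fell in 0, or 16 and 0 adjusted over the list alone (camera adjusted p = 6.27e-28). Nr5a2 rose by 3.05 ± 0.43 and Esrrb by 2.54 ± 0.38. Experiments differed. Esrrb was at 60.76, 50.74, 7.787 and 24.83 CPM with 2iL in experiments 1 to 4, and at 5.969, 5.961, 7.655 and 5.358 at 120 h. In experiment 3 Nanog was lower with 2iL than at 120 h (6.327 against 13.06 CPM), while Klf4 (16.06 against 12.16) and Tfcp2l1 (25.31 against 4.503) were higher. MEK and ERK targets fell in 7 of 15 cases and rose in 0, or 9 and 0 adjusted over the list alone (camera adjusted p = 8.19e-18). Dusp6 was at -3.32 ± 0.30 and Egr1 at -2.99 ± 0.68. Of 14 LIF and STAT3 targets 5 rose (3 without the 96 h + 2iL library of experiment 2) and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 2.55e-14). Bcl3 rose by 2.81 ± 0.43. Formative and primed epiblast genes fell in 5 of 19 and rose in 0, or 9 and 0 adjusted over the list alone (camera adjusted p = 2.53e-09). Etv4 was at -2.88 ± 0.43. WNT and beta-catenin targets rose in 4 of 13 and fell in 0, or 10 and 0 adjusted over the list alone (camera adjusted p = 5.31e-09). Notum rose by 3.14 ± 0.69. Mitosis and proliferation genes had 0 of 18 called, also adjusted over the list alone, and were lower as a list (camera adjusted p = 0.000814). Cholesterol biosynthesis genes had 0 of 21 called, also adjusted over the list alone, and were lower as a list (camera adjusted p = 0.00016, adjusted p = 0.18 with an estimated correlation).

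Mesendoderm and primitive streak genes rose against 120 h in 3 of 10 cases and fell in 1, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.00245, adjusted p = 0.198 with an estimated correlation, and 0.0642 with fry). Cdx2 was at 2.42 ± 0.46 and Eomes at -2.61 ± 0.60. Glycolysis genes fell in 2 of 19 and rose in 0, or 3 and 0 adjusted over the list alone (camera adjusted p = 0.00245, adjusted p = 0.198 with an estimated correlation, and 0.0642 with fry). Slc2a1 was at -0.98 ± 0.16. P53 targets rose in 1 of 16 cases, Cdkn1a at 1.48 ± 0.19, and fell in 0, the same adjusted over the list alone (camera adjusted p = 0.0272, adjusted p = 0.353 with an estimated correlation, and 0.157 with fry).

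The comparison of 48 h + 2iL with 2iL asks what still differed after the shorter withdrawal. Tfcp2l1 was at 373 ± 25.3 CPM against 550 ± 68.4 (log2 fold change -0.56, adjusted p = 0.159), and Esrrb at 163 ± 18.4 against 195 ± 28 (-0.26, adjusted p = 0.61). T was at 77.4 ± 29.0 CPM against 19.5 ± 6.54, a called rise of 1.99 ± 0.54 (log2) for this mesoderm gene. In all, 1288 genes changed, 680 up and 608 down, and 759 changed without the 48 h + 2iL library of experiment 3. The growth cone gene Gap43 (4.41 ± 0.47, adjusted p = 8.04e-08) rose. Ly6a (-4.65 ± 0.35, adjusted p = 9.49e-11) and the germ cell gene Dazl (-3.57 ± 0.43, adjusted p = 5.43e-07) fell. Vrtn (3.28 ± 0.69, adjusted p = 0.00147) lost its call with limma-voom (0.0752), and Pramel6, with 3 counts against 100 (ratio 33.7, 95% interval 11.2 to 166), lost it with DESeq2 (0.0676).

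None of the lists called between 48 h + 2iL and 2iL kept its call with an estimated correlation. Naive pluripotency genes fell in 3 of 17 cases (5 with the experiment as a block) and rose in 1, or 4 and 1 adjusted over the list alone (camera adjusted p = 0.00369, adjusted p = 0.56 with an estimated correlation, and 0.126 with fry). Tcl1 was at -2.11 ± 0.22 and Gbx2 at 1.43 ± 0.37. Formative and primed epiblast genes rose in 7 of 19 and fell in 1, or 8 and 3 adjusted over the list alone (camera adjusted p = 0.00369, adjusted p = 0.199 with an estimated correlation). Sox3 was at 2.69 ± 0.42. LIF and STAT3 targets fell in 5 of 14 and rose in 1, or 7 and 1 adjusted over the list alone (camera adjusted p = 0.00166, adjusted p = 0.199 with an estimated correlation). Klf4 was at -1.21 ± 0.24. Cholesterol biosynthesis genes rose in 3 of 21 (7 with the block, and 0 to 1 without the 2iL library of experiment 3 or 4 or the 48 h + 2iL library of experiment 3) and fell in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00369, adjusted p = 0.333 with an estimated correlation). Lss rose by 0.71 ± 0.21. Of 10 mesendoderm and primitive streak genes 5 rose (2 without the 48 h + 2iL library of experiment 3) and 0 fell, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.00451, adjusted p = 0.284 with an estimated correlation). Wnt3 rose by 2.19 ± 0.51. Neuron genes rose in 3 of 9 and fell in 1, or 6 and 1 adjusted over the list alone (camera adjusted p = 0.0266, adjusted p = 0.199 with an estimated correlation). Map2 rose by 2.52 ± 0.41.

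The comparison of 96 h + 2iL with 2iL asks the same after the longer withdrawal. Tfcp2l1 was at 88.7 ± 51.0 CPM against 550 ± 68.4, a fall with a log2 fold change of -2.62 ± 0.28. Zic1 and the neural tube factor gene Msx3 had 0 counts in 2iL and were at least 78.3-fold and at least 79.1-fold higher. The bound for Zic1 was 46.2 without the 96 h + 2iL library of experiment 3. Cdx2 rose by 2.84 ± 0.47. In all, 4540 genes changed, 2375 up and 2165 down. Hes3 had 345 counts against 1 (ratio 371, 95% interval 66.2 to 14700) and Stra6 had 319 against 1 (ratio 343, 95% interval 61.2 to 13600). Crxos fell (-5.91 ± 0.42, adjusted p = 1.4e-12), and Khdc3 had 1 count against 245 (ratio 228, 95% interval 40.5 to 9030).

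Naive pluripotency genes fell in 96 h + 2iL against 2iL in 16 of 17 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 7.33e-14). Tcl1 was at -4.61 ± 0.27 and Tbx3 at -3.53 ± 0.29. LIF and STAT3 targets fell in 12 of 14 and rose in 1, the same adjusted over the list alone (camera adjusted p = 3.74e-08). The LIF receptor gene Lifr was at -2.70 ± 0.24. Neural progenitor genes rose in 12 of 15 and fell in 1, the same adjusted over the list alone (camera adjusted p = 8.93e-05, adjusted p = 0.277 with an estimated correlation). Sox1 rose by 5.50 ± 0.57. Formative and primed epiblast genes rose in 11 of 19 and fell in 5, the same adjusted over the list alone (camera adjusted p = 0.00901, adjusted p = 0.228 with an estimated correlation). Lin28b was at 4.32 ± 0.40 and Etv4 at -3.35 ± 0.43. Cholesterol biosynthesis genes rose in 16 of 21 and fell in 1, the same adjusted over the list alone (camera adjusted p = 7.69e-05, adjusted p = 0.228 with an estimated correlation). Hmgcs1 rose by 1.46 ± 0.14. Mitochondrially encoded genes fell in 6 of 10 (3 without the 2iL library of experiment 3 or the 96 h + 2iL library of experiment 3 or 4) and rose in 0, or 7 and 0 adjusted over the list alone (camera adjusted p = 0.023, adjusted p = 0.306 with an estimated correlation). mt-Nd4 was at -1.10 ± 0.20.

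The difference of the responses to 2iL, after 96 h minus after 48 h, asks whether the genes responded differently. Each response also holds 24 h of culture, so a difference need not come from 2iL alone. Otx2 changed by -5.49 (log2) after 48 h and by -1.85 after 96 h, a difference of 3.64 ± 0.63 (adjusted p = 0.00224). Its 96 h + 2iL library of experiment 3 was at 224 CPM and the other 3 at 17.6 to 37.5. The tight junction gene Cldn3 rose by 2.10 after 48 h and fell by 2.07 after 96 h (difference -4.17 ± 0.79, adjusted p = 0.00564). Bdh1, an enzyme of ketone body metabolism, rose by 2.56 after 48 h, against -0.13 (not called, adjusted p = 0.869) after 96 h (difference -2.69 ± 0.46, adjusted p = 0.00224). Sall2 fell by 3.39 after 48 h, against -0.42 (not called, adjusted p = 0.513) after 96 h (difference 2.98 ± 0.57, adjusted p = 0.00647, and 0.0626 with limma-voom).

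In this test 102 genes differed, 50 with a positive and 52 with a negative difference. The count was 194 with the experiment as a block, 168 with DESeq2, 64 with limma-voom and 321 with no filter. It was 54, 49 and 55 without the 48 h library of experiment 1, 3 or 4, 66, 56 and 62 without the 48 h + 2iL library of experiment 1, 2 or 4, 50 without the 96 h library of experiment 4, and 54 and 51 without the 96 h + 2iL library of experiment 3 or 4. The other 11 named genes each lost the call without at least 1 library, and the highest adjusted p is given for each. Without a 96 h + 2iL library it was 0.0604 for Dll1 (difference 4.19 ± 0.92, adjusted p = 0.0197; experiment 4), 0.172 for Tshz3 (3.00 ± 0.76, 0.0464; experiment 4), 0.143 for Cdk5r2 (3.00 ± 0.69, 0.0277; experiment 3) and 0.145 for Pou3f1 (2.65 ± 0.62, 0.0298; experiment 3). Without a 48 h library it was 0.0841 for Sparcl1 (4.03 ± 0.82, 0.00879; experiment 1), 0.085 for Pogk (2.799 ± 0.66, 0.0301; experiment 4), 0.0671 for Iglon5 (-3.77 ± 0.85, 0.0224; experiment 3) and 0.0841 for Pdlim4 (-3.19 ± 0.74, 0.0277; experiment 1). Without the 96 h library of experiment 4 it was 0.0811 for Pdzrn4 (-4.20 ± 0.98, 0.0293) and 0.0745 for Cttnbp2 (-3.11 ± 0.69, 0.0205), and without the 48 h + 2iL library of experiment 4 it was 0.0587 for Ephb1 (-3.14 ± 0.68, 0.0178). With limma-voom 11 of the 16 genes named by the rule lost the call, with an adjusted p of up to 0.253 (Pou3f1).

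Of the lists, formative and primed epiblast genes had a positive difference of responses in 2 of 19 cases, Otx2 and Pou3f1, and a negative one in 0, or 5 and 0 adjusted over the list alone (camera adjusted p = 0.00484, adjusted p = 0.199 with an estimated correlation, and 0.0761 with fry). Naive pluripotency genes had 0 of 17 called, or 2 negative adjusted over the list alone (camera adjusted p = 0.00521, adjusted p = 0.692 with an estimated correlation, and 0.468 with fry). Tfcp2l1 was at -1.53 (adjusted p = 0.123) and Esrrb at -0.43 (adjusted p = 0.817). Neuron genes had 1 of 9 called, Map2 at -2.59 ± 0.52, or 3 negative adjusted over the list alone (camera adjusted p = 0.0101, adjusted p = 0.192 with an estimated correlation). Mesendoderm and primitive streak genes had 0 of 10 called, also adjusted over the list alone (camera adjusted p = 0.0101, adjusted p = 0.468 with an estimated correlation, and 0.189 with fry).

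Genes that changed on withdrawal and went the opposite way with 2iL numbered 1231 after 48 h, 40.0% of the 3081 withdrawal calls, with 629 that rose and then fell and 602 that fell and then rose. Independent calls would give 230, and comparisons that take the 48 h libraries 2 and 2 gave 589 (89.4 if independent) and 670 (88.2). The 20 simulated sets of unchanged groups gave 1 at most. With no gene changed on withdrawal a count near 0 was built in, so they give no support. Of the 1231, 1001 were not called against 2iL, 207 were still called on the side of withdrawal and 23 were called past the 2iL level. After 96 h there were 538, 11.8% of 4557, with 345 that rose and then fell and 193 that fell and then rose. Independent calls would give 212.4, and the comparisons with 2 and 2 libraries gave 301 (125.6) and 207 (53.1). Simulated sets gave 0, with the same limit. Of the 538, 318 were not called against 2iL, 208 were still called and 12 were past it. Genes called on withdrawal that moved further in the same direction with 2iL numbered 118 after 96 h and 13 after 48 h. These comparisons also differ by 24 h of culture, so such moves cannot be told apart from time alone. Without 2iL the 96 h share also went from 0.96 at 96 h to 1.042 at 120 h. The responses to 2iL after 48 h and after 96 h shared 211 rises (32.2 if independent) and 287 falls (44.4), Tfcp2l1 and Pou3f1 among them, and had a Pearson r of 0.572 across genes, which are not independent replicates.

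The retained share of the withdrawal change was 0.440 ± 0.052 in 48 h + 2iL and 0.850 ± 0.115 in 96 h + 2iL (SD, n = 4). The difference of 0.410 had an exact permutation p of 0.0286, two-sided, the smallest that 4 against 4 can give. Sign flips within the 4 experiments, which keep the pairing, gave 0.125, the smallest they can give, so the call is not kept in that test. On the scale of the 48 h change, 24 h libraries had a share of 0.607 ± 0.024, 48 h libraries 0.952 ± 0.047 and 96 h + 2iL libraries 0.713 ± 0.085. On the scale of the 96 h change, 48 h libraries had 0.575 ± 0.066, 120 h libraries 1.04 ± 0.026 and 48 h + 2iL libraries 0.376 ± 0.069. Cells of 48 h + 2iL were 72 h past the first withdrawal, and no group withdrawn for 72 h was analysed here.

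**Figure D3:**
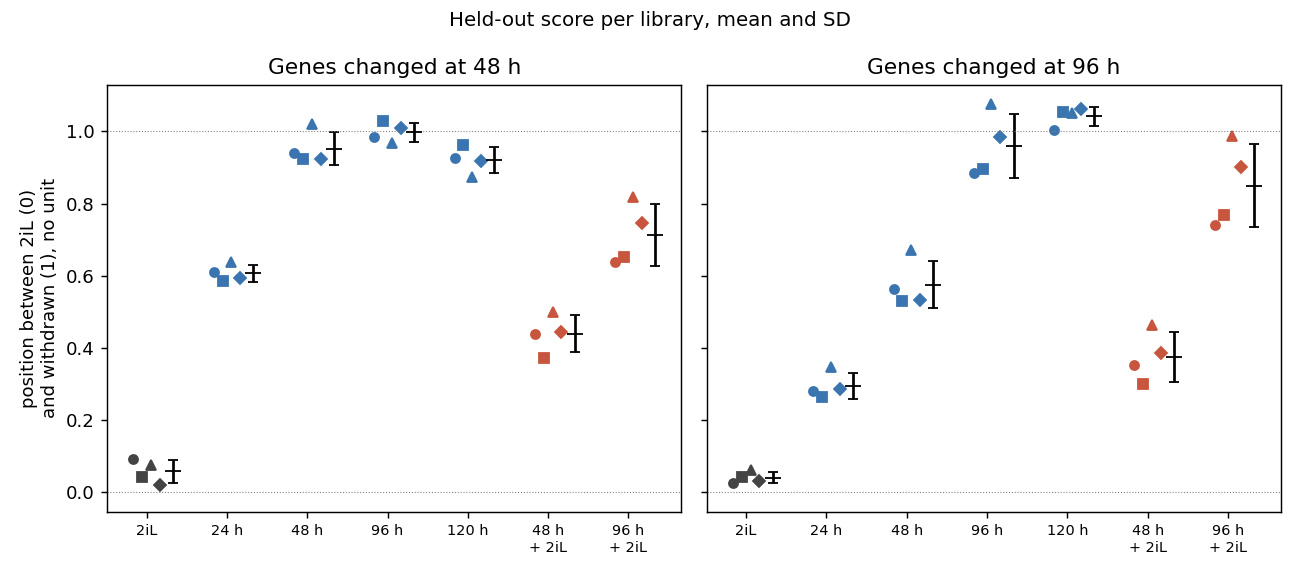
Points give the retained share of each library, from 0 at the 2iL level to 1 at the withdrawn level, with the mean and SD of 4 libraries per group, for genes changed at 48 h (left) and at 96 h (right). The share averaged 0.440 in 48 h + 2iL on the left and 0.850 in 96 h + 2iL on the right.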

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

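The tests of depth, of exchanged labels and of mixed cells were chosen only after the result was seen, and the test of exchanged labels was changed several times after its scores were seen.

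A test of the difference between the responses to 2iL after 96 h and after 48 h picked out 102 genes, and the retained share differed by 0.4101. Among the named genes, log2 differences were 4.19 (Dll1), 4.03 (Sparcl1), 3.64 (Otx2), 3.00 (Tshz3), 3.00 (Cdk5r2), 2.98 (Sall2), 2.799 (Pogk), 2.65 (Pou3f1), -4.20 (Pdzrn4), -4.17 (Cldn3), -3.77 (Iglon5), -3.19 (Pdlim4), -3.14 (Ephb1), -3.11 (Cttnbp2) and -2.69 (Bdh1). Among lists, naive pluripotency (camera adjusted p = 0.00521), formative and primed epiblast (0.00484), neuron (0.0101) and mesendoderm and primitive streak (0.0101) differed, and none kept the call with an estimated correlation.

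In 25 of 196 groups of 4 values, 1 library lay apart from the other 3, its gap to the nearest being so large a part of the whole range that it passed Dixon's 95% criterion. Chance gives about 1 in 20 (5.02% of simulated groups of normal values), a rate that need not hold near 0 counts, and in 6 of the 25 the other 3 libraries were at 0. Experiment 3 held Otx2 at 223.9 CPM in 96 h + 2iL (others 17.56 to 37.54), Pax6 at 17.88 CPM at 96 h (2.294 to 4.867) and 11.19 in 96 h + 2iL (1.238 to 1.899), and Zic1 at 6.541 CPM at 96 h (0 to 0.9175), 67.1 at 120 h (11.56 to 20.09) and 0.4156 in 48 h + 2iL (others 0). It also held Cdx2 at 0.6104 CPM at 48 h, Hoxb1 at 0.63 at 24 h and 0.6104 at 48 h (others 0), 2.763% mitochondrial counts in 2iL (2.225 to 2.243) and 8.294% of reads outside genes in 2iL (7.647 to 7.701). Experiment 1 held 14923 genes detected at 120 h (14309 to 14372), 1.985% mitochondrial counts at 96 h (1.704 to 1.725), 7.764% ribosomal protein counts at 48 h (8.066 to 8.106), 7.055% of reads outside genes at 48 h (6.811 to 6.841), 25.016% of counts in the 10 most abundant genes in 48 h + 2iL (21.495 to 22.07), Klf4 at 19.77 CPM at 120 h (12.16 to 12.95) and Esrrb at 190.6 CPM in 48 h + 2iL (152.2 to 157.3). Experiment 2 held Pax6 at 0 CPM in 2iL (0.9662 to 1.136) and 4.443 at 48 h (2.074 to 2.453), T at 0.4713 CPM at 24 h (others 0) and Hoxb1 at 4.722 CPM in 2iL (0 to 0.4831). Experiment 4 held Cdx2 at 0.6911 CPM at 24 h (others 0) and 1.217 at 96 h (0.4043 to 0.4587), and Hoxb1 at 91.87 CPM in 96 h + 2iL (11.39 to 23.51).

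Each comparison was repeated on the 35 splits of its 8 libraries (for the difference of responses, of 8 pairs of a withdrawn and a re-induced library). The real split gave the most genes in all 10 comparisons (1 of 35 splits each), the smallest share this test can give. That share is under 0.05 only if all 35 are taken as alike, and it is not adjusted over the 10 comparisons. Since experiments pair the libraries, the 8 splits that part the libraries of every experiment are the closer comparison, and they are too few for a share under 0.05. The real count and the highest other were 1770 and 133 for 24 h, 3081 and 13 for 48 h, 4557 and 13 for 96 h and 5239 and 12 for 120 h against 2iL. They were 1652 and 2 for 48 h + 2iL against 48 h, 1288 and 5 for it against 2iL, 4540 and 33 for 96 h + 2iL against 2iL, and 102 and 1 for the difference of responses. For 96 h + 2iL they were 1024 and 538 against 96 h and 291 and 258 against 120 h, which points to a structure of the samples. Among the 7 other splits that part every experiment, the highest were 67 and 51 for these comparisons and 0 to 25 for the other 8. Splits of experiments 1 and 2 against 3 and 4 gave 185 and 256 genes, and counts with the experiment as a block were 1339 and 413.

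The 96 h library of experiment 3 lay further from 2iL than the other 96 h libraries. On the 96 h share, experiment 3 was also highest in each other group except 120 h. It had 0.3465 at 24 h, 0.6704 at 48 h, 0.4637 in 48 h + 2iL and 0.9871 in 96 h + 2iL. The group means were 0.295, 0.575, 0.376 and 0.850. Its 96 h library had 2178323 counts, within the range of 2145440 to 2553721 at 96 h, so depth did not set it apart. Thinning all libraries to the lowest total left the gap in the 96 h share at 0.157 against 0.153 without. With such totals thinning could hardly change the gap, so it adds no support. An axis ran from the 96 h level (0) to the 120 h level (1) of the other 3 experiments, over 200 genes. On it experiment 3 lay at 0.97 in its library labelled 96 h and at 1.468 in that labelled 120 h. The difference of 0.498 is above 0, where an exchange would put it below. The other differences were 0.575, 0.771 and 0.802 (SD 0.123) for experiments 1, 2 and 4. Without these experiments 50, 0 and 0 genes were called between 96 h and 120 h, against 445 without experiment 3, so this SD is a weak measure. On the retained share the order was 1.0497 at 120 h and 1.0747 at 96 h, with 1.0396 for the other 120 h libraries. The test was changed after its scores were seen, so it does not decide about exchanged labels. A candidate explanation is that cells of experiment 3 were ahead in time, which was not tested.

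Naive genes were higher in 96 h + 2iL than at 120 h. Cells in the 2iL state mixed in would return all genes by 1 share, but 36 genes nearly absent at 120 h returned a median of 4.947% of their 2iL level (quartiles 2.519 to 9.62) against 14.619% for the 10 naive genes that rose. The naive genes were picked for rising and ranged from 3.01% to 42.88%, and 5 of the 36 lay above their median. In experiment 3 Tfcp2l1 was at 25.31 CPM in 96 h + 2iL and 4.503 at 120 h, Klf4 at 16.06 and 12.16, Esrrb at 7.787 and 7.655, and Nanog at 6.327 and 13.06. All 10 stayed called with library totals alone, where rises over all genes went from 142 to 115. The choice between these scalings thus did not make the calls. It moved the median of all genes by only -0.056 (log2) and could hardly have removed them, so it decides nothing further about TMM. A return in part of the cells, or a partial return in all of them, may be at work, and bulk counts cannot separate these.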

How the results depend on the processing

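The alternatives that leave out experiment 3 and that score libraries against their own experiment were chosen only after the result was seen. No sign turned under an alternative among the 160 named genes, the 82 list calls and the retained share. Genes and lists were picked for being called, so this was nearly built in. Signs of other values were not followed. The balance of rises and falls turned with library totals in 2 comparisons, to 1492 and 1544 at 48 h (1616 and 1465 with TMM) and to 879 and 728 for 48 h + 2iL against 48 h (802 and 850). A 2-fold minimum gave 942, 1715, 2795 and 3252 genes at 24, 48, 96 and 120 h, 923 for 48 h + 2iL against 48 h, 607 for 96 h + 2iL against 96 h, 728 and 2828 for 48 h + 2iL and 96 h + 2iL against 2iL, and 657 and 319 reversed genes, as its construction requires. For 96 h + 2iL against 120 h, no filter gave 493 and only the groups compared gave 115. For the difference of responses, no filter gave 321, DESeq2 168, limma-voom 64 and the block 194, and the cause was not tested. Leaving out 1 library gave 1376 to 1770 genes at 24 h, 2606 to 2930 at 48 h, 4078 to 4381 at 96 h and 4786 to 5079 at 120 h, 1290 to 1357 for 48 h + 2iL against 48 h, 658 to 1323 for 96 h + 2iL against 96 h, 158 to 450 against 120 h, 759 to 1266 for 48 h + 2iL against 2iL, 3912 to 4495 for 96 h + 2iL against 2iL, 49 to 136 for the difference, and 941 to 1011 and 384 to 604 reversed genes. Without experiment 3 the 10 counts were 1410, 2583, 3837, 4540, 1312, 1123, 422, 887, 3712 and 70. The difference in retained share was 0.3543 to 0.4272 without 1 experiment (exact p 0.1, the smallest possible), 0.4101 by sign flips within experiments (exact p 0.125, the smallest possible) and 0.3885 to 0.4516 under the other alternatives. Of 82 list calls, 39 held with an estimated correlation, 74 with fry and 81 with the block. The block also moved 4 counts within lists by over 1.5 times, where only the groups compared moved 19, no filter 16, limma-voom 12, leaving out experiment 3 10, DESeq2 2, library totals 1 and the 2-fold minimum 38. Leaving out 1 library moved 22 of 146 such counts. The block left the call of all 160 named genes and gave 194 genes for the difference against 102, while its sign flips cannot reach 0.05 for the retained share. Of 160 named genes, 13 lost the call without some library, 13 with limma-voom, 2 with DESeq2, 8 without experiment 3 and 2 under another alternative. Most of these losses were among the 16 named genes of the difference of responses, with 11, 11, 0, 8 and 2 in the same order. Scaling by library totals left 34 positive and 54 negative differences of responses (38.6% positive against 49.0%). Depth limits genes with few counts, and the simulation recovered 21.7% of 1.5-fold changes.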

Other observations

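The lists of this part and the test against further culture were chosen only after the result was seen. Hox, Cdx and Evx genes, which pattern the body axis, rose in 96 h + 2iL against 96 h in 9 of 10 measured genes and fell in 0, the same adjusted over the list alone (camera p = 9.21e-16, and 0.000397 with an estimated correlation). The list holds 57 genes, and only these 10 passed the filter on counts. A gene can pass it through the 96 h + 2iL libraries themselves, as with Hoxb4 (17.36 CPM there, 2.879 in 2iL). The count and its p therefore restate what had been seen and are not separate support. Hoxb4 (log2 fold change 4.41 ± 0.81), Cdx1 (3.80 ± 0.82), Hoxc4 (3.62 ± 0.74) and Hoxb9 (2.55 ± 0.68) were among them. In 48 h + 2iL against 48 h, 5 of the 10 rose and 0 fell, the same adjusted over the list alone, with a camera p (limma) of 9.74e-08. At 24 h against 2iL 0 rose and 6 fell, or 0 and 7 adjusted over the list alone, with a camera p (limma) of 7.73e-06. At 120 h against 2iL, also without 2iL, 2 rose and 4 fell, the same adjusted over the list alone, with a camera p (limma) of 0.137. There Hoxb1 was at 3.19 and Hoxb8 at 3.45 (log2), and Cdx2 at 0.43 (adjusted p = 0.507).

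Imprinted genes rose at 120 h against 2iL in 10 of 20 measured cases and fell in 3, the same adjusted over the list alone (camera p = 0.00523, and 0.0155 with an estimated correlation). Peg12 rose by 5.02, Nnat by 4.09, Grb10 by 3.65 and H19 by 3.43 (log2), while Plagl1 was at -3.51. In 96 h + 2iL against 2iL, 9 of the 20 rose and 3 fell, or 11 and 4 adjusted over the list alone, with a camera p (limma) of 0.0111. Against 96 h, 1 rose and 4 fell, or 5 and 6 adjusted over the list alone, with a camera p (limma) of 0.513. H19 differed between experiments, at 123.9, 105.5, 13.52 and 27.58 CPM in experiments 1 to 4 at 96 h and at 104.4, 83.74, 14.6 and 34.76 CPM in 96 h + 2iL.

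The posterior genes that rose in 96 h + 2iL against 96 h could have risen with 24 h of further culture alone. Against 120 h their median log2 fold change was 1.611 (SD 0.844 over 9 genes, which are not replicates). The genes were picked for being high in these same 96 h + 2iL libraries, which can raise the median by an unknown amount. It therefore cannot decide against time alone for the set. Adjusted over all genes, Cdx2 (2.42, adjusted p = 0.0017) and Hoxb4 (3.33, adjusted p = 0.00684) were called singly against 120 h. Adjusted over the list alone, 8 of the 10 measured genes rose and 0 fell, 7 of them among these 9 genes, with a camera p (limma) of 1.72e-08, and 0.00502 with an estimated correlation. The choice of the list and the filter bear on this p as well. Hoxb1 is among the 7 (edgeR p of 0.046 adjusted over the list alone). It was at 91.87 CPM in the 96 h + 2iL library of experiment 4 and at 11.39 to 23.51 in the others, with a mean of 12.91 at 120 h. Cdx1, Cdx2, Hoxb4, Hoxb8 and Hoxc4 were higher than at 120 h in 4 of 4 experiments. Hoxb8 and Hoxb9 were called in neither way, so time stays open for them too. All 9 genes stayed called with library totals alone, but that scaling moved the median of all genes by only 0.007 (log2) here, so this decides nothing about TMM. A response of posterior genes to the inhibitors or to LIF may be at work, and which component acts was not tested.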
